A study of Homo sapiens with 2 samples.

How the data were processed

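Single-cell RNA was measured in 2 libraries, 1 labelled MP41 and 1 labelled LX2, both from human cell cultures. The deposited matrices hold raw UMI counts per gene and barcode for 33538 genes, made by the authors with Cell Ranger on GRCh38, per the submitters' processing notes. The Cell Ranger version is not given in the sources used here, and neither is the filter that set the barcodes. Each matrix was tied to its library by the library name, which equals the title in the labels. The labels name MP41 alone and MP41 with LX2 as the cultures but do not assign either to a library, and no condition was assigned here.

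Cells with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, which removed 426 and 173 barcodes from the libraries labelled MP41 and LX2. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were picked with scanpy 1.11.5, and 30 principal components and 15 nearest neighbours gave a graph that was clustered with the Leiden method in igraph 0.11.9 at resolution 0.5. An earlier run with a weighted, approximate neighbour graph was replaced by this exact one, after its output had been seen, so that repeated runs give identical values. Clusters were named from markers fixed before the data were examined. The scoring rule was set after the data were seen: a cluster was mixed if its summed CPM of both marker sets reached 10% of the highest cluster of at least 100 cells, and named if its own reached 30% and the other stayed below 10%, with at least 3 detected markers. A cluster so named was set back to unnamed if its median depth lay below 1/3 of its library's and its 10 leading genes held none of its markers, or if they held more markers of another type. This kept 394 mixed and 81 unnamed cells of the library labelled MP41 and 9 unnamed cells of the library labelled LX2 out of both classes. The unnamed cells passed the marker rule for uveal melanoma-like cells and were kept out by the depth clause alone. With the library labelled MP41 clustered alone, a similar cluster of 64 cells at 0.347 of the median depth was named uveal melanoma-like. Scrublet, run per library in scanpy, was used for doublets.

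Counts were summed over the cells of a library or class and scaled to the summed total (CPM). A gene at 0 was set to a floor of 3 counts. With 1 library per label no test was made, and differences were described by ratio, with exact Poisson, conditional Poisson or Clopper-Pearson intervals at 95% that cover counting error only. Genes were counted at a ratio of at least 4 and 10 CPM or more. Named genes were the 12 with the largest ratio in each direction at 50 CPM or more (10 for a class in both libraries), up to 2 per gene list and direction at 2-fold or more, GDF15, GFRAL and RET, the 8 leading ligand and receptor pairs per direction by the product of their CPM among pairs with a ligand at least 4-fold higher in the sender, and the 10 leading genes of a cluster at 50 CPM or more. The text gives part of these, and 1 gene is not reported here. HMGN5 between libraries, PMEL, TYRP1, LOX and CXCL8 between classes, S100A6 and TMSB4X in uveal melanoma-like cells, STAT3, JUNB, IL6, LIF and IL11 were named after their values were seen. The median log2 ratio of each of 33 gene lists was set against 10000 random lists matched on expression in 20 bins, which describes these libraries only. XIST, TSIX and genes on chromosome Y were left out throughout. Gene positions are from GENCODE 29.

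The level that free RNA of the other class may bring was taken as the 95th percentile of the level of class markers in the other class. For uveal melanoma markers this was 3.68% over 11 genes. RAB27A was left out of it after its value had been seen. With it the percentile was 15.7%. For stellate-like RNA in uveal melanoma-like cells it was 1.21%, over 61 genes at 100 CPM or more in stellate-like cells and below 1 CPM in uveal melanoma-like cells of the library labelled LX2. For shares of cells and phase calls each cell was thinned to 4500 UMIs. Alternatives covered the cell filter, doublets, scaling (TMM in edgeR 4.0.16, totals without mitochondrial and ribosomal genes, mean of each cell's CPM), thinning, floors, ratios, resolution, variable genes, clustering each library alone and, added after seeing the data, stellate-like RNA taken off (for lists with all members kept), naming without the depth clause and 4 bins of cells by depth.

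The steps were tested on simulated data. For the comparison of libraries over 33436 genes, 50 genes were raised at each fold in the library labelled MP41. The 4-fold rule called 0 of 50 at 3-fold, 34 of 50 at 5-fold and 50 of 50 at 8-fold, and 0 unchanged genes. Raised genes take counts from the total, so a 5-fold change measured 4.02. Of 100 unchanged lists, 4 fell outside the middle 95% of random lists. Simulated cells of each class and 60 simulated pairs were all named as made, from profiles that the same markers had defined. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.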

Results

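Single-cell RNA sequencing on a droplet platform was used to profile human cultures collected after 72 hr of culture. The 2 libraries carry the names of 2 cell lines. MP41 is a uveal melanoma line, derived from the pigment cell tumour of the eye, and LX2 is a line of hepatic stellate cells, the matrix-producing cells of the liver. The labels describe cultures of MP41 alone and of MP41 with LX2, and do not say which library came from which. The library labelled MP41 held 7149 barcodes with 99294711 unique molecular identifiers (UMIs), and the library labelled LX2 held 4079 barcodes with 59319230 UMIs. After filtering, 6723 cells with a median of 13707 UMIs and 3469 genes remained in the former, and 3906 cells with a median of 14566 UMIs and 3692 genes in the latter. Their median mitochondrial shares were 2.55% and 4.72%, and ribosomal genes held 27.8% and 25.9% of their UMIs. With 1 library per label there was no replicate and no test between groups. Every interval below is a 95% interval that covers counting error only.

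The cell types found went against the label of the library labelled LX2, so both libraries are named by their label throughout. Of its 3906 cells, 3896 were uveal melanoma-like (99.7%, exact binomial interval 99.5 to 99.9%) and 1 was stellate-like (0.0256%, interval 0.000648 to 0.143%). The library labelled MP41 held both classes. In it 3929 of 6723 cells were uveal melanoma-like (58.4%, interval 57.3 to 59.6%) and 2319 were stellate-like (34.5%, interval 33.4 to 35.6%). A further 394 of its cells (5.86%) formed a cluster with markers of both classes, and 81 (1.205%) stayed unnamed. The library labelled LX2 held 0 of 3906 cells of the former kind (exact upper bound 0.0944%) and 9 of the latter. Pigment cell genes marked the first class. PMEL, a melanosome structural protein, stood at 2214 CPM in the uveal melanoma-like and 64.3 CPM in the stellate-like cells of the library labelled MP41, and the melanosomal enzyme TYRP1 at 2330 and 58.8 CPM. The collagen crosslinking enzyme LOX stood at 29.2 CPM in the first and 4015 CPM in the second, and COL1A1, a chain of type I collagen, at 3.72 and 595 CPM. Stellate-like cells were shallower, with a median of 7728 UMIs against 17387. Scrublet called 4 of 6723 and 17 of 3906 cells doublets, a rate too low to have worked in the library labelled MP41, so doublets were not removed.

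**Figure D1:**
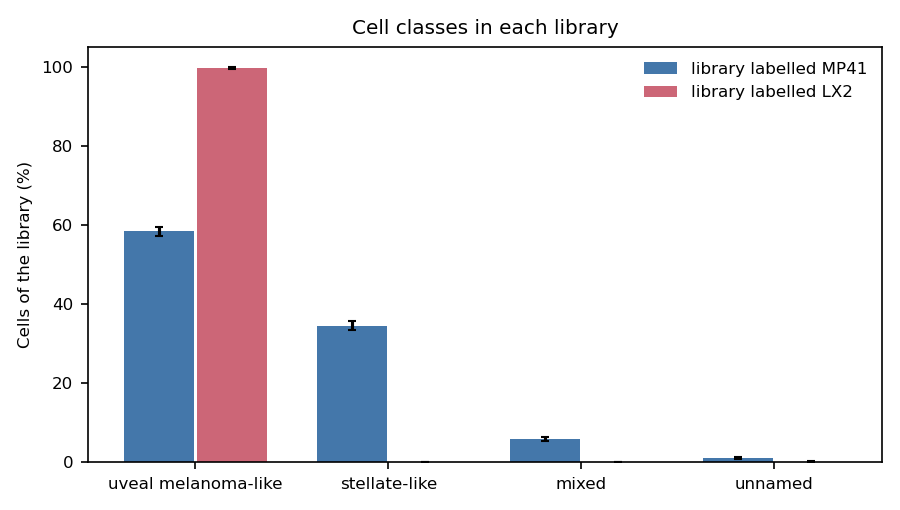
Share of each library's cells (%) in each class, with exact binomial 95% intervals. The library labelled MP41 holds 58.4% uveal melanoma-like and 34.5% stellate-like cells, and the library labelled LX2 99.7% uveal melanoma-like cells.

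The summed libraries were compared first, as the labels imply. In the library labelled MP41, 237 genes were at least 4-fold higher, and 1 gene, HMGN5, a nucleosome-binding protein, was at least 4-fold higher in the library labelled LX2 (37.8 against 9.17 CPM; it was named after its value was seen). Large ratios belonged to genes of the stellate-like cells. Among them, LOX stood at 896 against 0.339 CPM and the actin-binding TMSB4X at 692 against 0.135 CPM. Among genes at 50 CPM or more, those furthest higher in the library labelled LX2 were the heat shock gene HSPA1B at 3.63-fold, the fatty acid synthase FASN at 3.51-fold, the chaperone HSP90AA1 at 3.20-fold and the melanosomal transporter SLC45A2 at 3.20-fold. With only the uveal melanoma-like cells of both libraries, the counts were 14 and 0 genes before stellate-like RNA was taken off.

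Within the library labelled MP41, stellate-like cells differed widely from uveal melanoma-like cells, a comparison chosen after the cell classes had been seen. Among 8983 genes at 10 CPM or more in either class, 1173 were at least 4-fold higher in stellate-like and 638 in uveal melanoma-like cells. This split depends on scaling, with 854 and 936 genes under TMM scaling, which lowered the log2 ratio of all genes by a median of 0.42. Among genes at 50 CPM or more, the largest ratios in stellate-like cells included the vasoconstrictor EDN1 (99.2 against 0.342 CPM, 290-fold, interval 194 to 454), the natriuretic peptide NPPB (272-fold), the activin subunit INHBA (266-fold), the actin-binding TAGLN (233-fold), the cytokine IL1B (229-fold) and the keratin KRT18 (227-fold). In uveal melanoma-like cells they included CPN1 (58.0-fold), the transporter SLC16A6 (52.7-fold), the chromatin remodeller ATRX (51.0-fold), the melanin enzyme DCT (48.4-fold), TRPM1 (45.7-fold), the tumour antigen PRAME (44.9-fold) and GDF15 (44.0-fold). Free RNA may hold these ratios down, which was not told apart from low expression. Of 12 uveal melanoma markers at 50 CPM or more, 11 stood in stellate-like cells at 2.06 to 3.78% of their uveal melanoma-like level, and RAB27A at 30.3%.

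Gene lists fixed before the data were examined followed the same division. Of the pigment and melanocyte lineage list, all 23 measured members were at least 2-fold higher in uveal melanoma-like cells. Of the fibrillar collagens and interstitial matrix, 19 of 22 were at least 2-fold higher in stellate-like cells, among them VCAN at 197-fold and COL1A1 at 160-fold, while COL11A1 was 24.0-fold higher in uveal melanoma-like cells. The contractile myofibroblast list had 14 of 15 members higher in stellate-like cells, and the TGF-beta response list 13 of 16. Of the inflammatory cytokines, 18 of 19 were higher there, with the neutrophil chemokine CXCL8 at 828 against 6.58 CPM, and MIF was 2.25-fold higher in uveal melanoma-like cells. Of the MHC class I presentation list, 8 of 13 were higher in stellate-like cells, including PSMB9 at 20.5-fold. Oxidative phosphorylation genes lay the other way, with 14 of 24 at least 2-fold higher in uveal melanoma-like cells and a median log2 ratio of -1.06. S phase genes (29 of 43) and G2 and M phase genes (31 of 54) were higher in stellate-like cells.

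GDF15, a secreted stress-induced member of the TGF-beta superfamily and the gene named in the title of the series, was a transcript of the uveal melanoma-like cells. The gene (ENSG00000130513) spans positions 18374731 to 18389176 of chromosome 19 on the forward strand in the GENCODE 29 annotation of GRCh38. In the library labelled MP41 it stood at 2718 CPM (exact Poisson interval 2706 to 2730) in uveal melanoma-like cells and at 61.8 CPM (58.4 to 65.4) in stellate-like cells. The latter is 2.27% of the former, within the range of the 11 melanocytic markers. Free RNA could bring such a level, but it was not told apart from low expression in stellate-like cells. In the uveal melanoma-like cells of the library labelled LX2 it stood at 1330 CPM (1321 to 1340), so the library labelled MP41 was 2.04-fold higher (2.03 to 2.06). Over all cells the values were 2123 and 1331 CPM, a ratio of 1.60 (1.58 to 1.61), which the stellate-like cells dilute. When each cell was thinned to 4500 UMIs, 88.6% of uveal melanoma-like cells of the library labelled MP41 and 78.6% of those of the library labelled LX2 had a GDF15 UMI, against 21.0% of stellate-like cells. Thinning left out 150, 62 and 423 cells, and without it the shares were 95.2%, 89.2% and 34.1%, at median depths of 17387, 14586 and 7728 UMIs. GFRAL, the receptor of GDF15 in the hindbrain, had 0 UMIs in both libraries, with exact upper bounds of 0.0374 and 0.0625 CPM. RET, its coreceptor, stood at 1.00 and 0.610 CPM.

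GDF15 varied between clusters within each library. In the clusters found with both libraries together, it was higher in the library labelled MP41 in each of the 4 uveal melanoma-like clusters. The values were 3089 against 2181 CPM in cluster 1, 2526 against 1617 in cluster 2, 877 against 540.2 in cluster 4, led by the mitotic genes ASPM and PLK1, and 1770 against 884 in cluster 5, led by histones and RRM2. Cluster 1 held 3136 of the cells of the library labelled MP41 and 196 of the other, and cluster 2 held 141 and 2569. GDF15 is among the genes that define cluster 1. In clusters drawn from the library labelled LX2 alone, GDF15 ranged from 478 CPM in 491 cells led by PIF1, FAM83D and NEK2 to 2334 CPM in 389 cells led by CREB5, SFRP1 and DDIT4, with the stress response genes TRIB3, ASNS and XBP1 among their 10 leading genes.

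**Figure D2:**
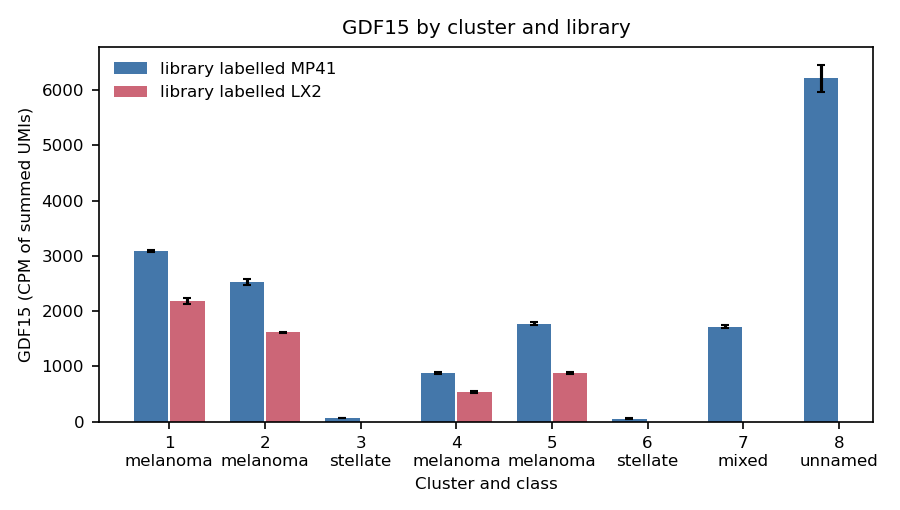
GDF15 in CPM of summed UMIs for each cluster of both libraries together, with exact Poisson 95% intervals, for groups of at least 50 cells. GDF15 is near 3089 CPM in cluster 1 of the library labelled MP41 and at 64.3 and 51.1 CPM in the stellate-like clusters 3 and 6.

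Uveal melanoma-like cells occurred in both libraries and were compared as a class, with most of them in cluster 1 in the library labelled MP41 and in cluster 2 in the library labelled LX2. At the 4-fold rule, 14 genes were higher in the library labelled MP41 and 0 in the library labelled LX2, and at 2-fold the counts were 78 and 163. With stellate-like RNA taken off each gene, a setting chosen after seeing the data, the 4-fold counts were 9 and 1 at a share of 1.21%. They were 9 and 11 at the highest share of 2.43%, which is that of 1 gene, OSMR. Of the 14 genes, 4, among them LOX, S100A6 and TMSB4X, exceeded their level in the library labelled LX2 by 0.543 to 0.725% of their stellate-like level. These lay within the 1.21% that stellate-like RNA may bring, and 10 exceeded that bound. LOX, S100A6 and TMSB4X are among the 61 genes that set the bound, so their place within it decides nothing about their source. Several of the leading genes, A2M and CEBPD among them, also define cluster 1. The largest ratios at 50 CPM or more belonged to the glucose transporter SLC2A3 (150 against 12.6 CPM, 11.9-fold, interval 11.03 to 12.8), the transcription factor CEBPD (501 against 56.4 CPM, 8.88-fold), the protease inhibitor A2M (285 against 35.7 CPM, 7.98-fold) and the transcription factor BHLHE40 (369 against 64.9 CPM, 5.68-fold). FOSL2, SPSB1, FOXF1, GLUL, UPP1 and HILPDA were 3.96-fold to 3.31-fold higher. At the same floor, the genes furthest higher in the library labelled LX2 were FASN (63.3 against 17.4 CPM, 3.64-fold), HSPA1B (3.21-fold), ATAD2 (3.10-fold), ID3 (3.08-fold) and the cell cycle transcription factor MYBL2 (3.01-fold). HSP90AA1 stood at 3808 against 1396 CPM. In GRCh38, CEBPD lies on chromosome 8 at 47736909 to 47739086 and A2M on chromosome 12 at 9067664 to 9116229, both on the reverse strand.

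**Figure D3:**
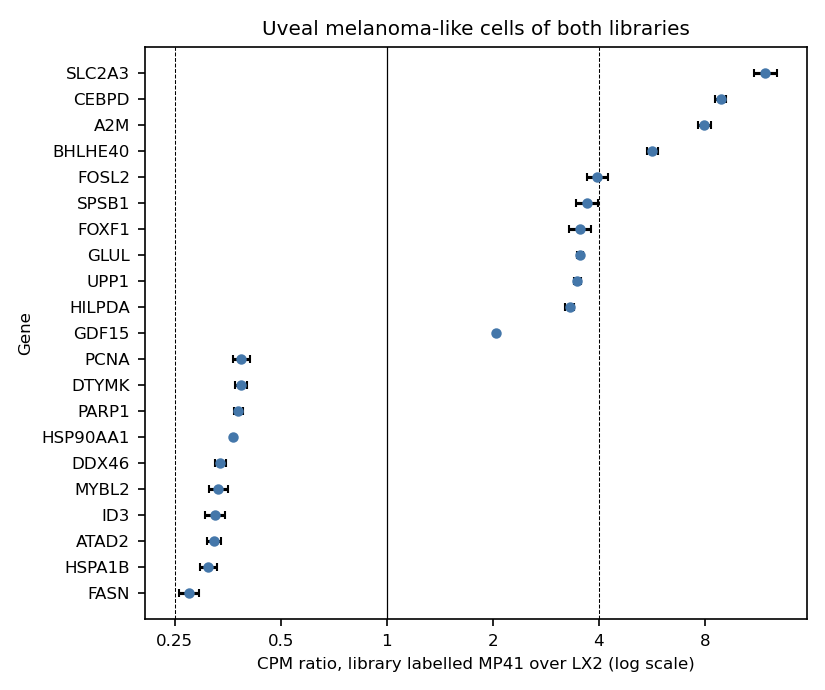
CPM ratio of the library labelled MP41 over the library labelled LX2 in uveal melanoma-like cells (log scale) for GDF15 and the 10 genes furthest in each direction at 50 CPM or more, with exact counting 95% intervals. Dashed lines mark the 4-fold rule, which SLC2A3, CEBPD, A2M and BHLHE40 pass.

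Among the fixed lists in this comparison, S phase genes stood furthest below, with 22 of 42 members at least 2-fold higher in the library labelled LX2 and a median log2 ratio of -1.02, at percentile 0 of 10000 matched random lists. G2 and M phase genes had a median of -0.65 and 4 of 54 members past 2-fold. The interferon response list had a median of 0.36, with IFITM3 at 325 against 118 CPM and 3 of 16 members at least 2-fold higher in the library labelled MP41 and 1 at least 2-fold lower. Medians above those of nearly all random lists were also found for the inflammatory cytokines (0.95, 4 of 8 past 2-fold), the TGF-beta response (0.49, 5 of 14) and YAP and TEAD targets (0.27, 2 of 17). The epithelial (2.46, 2 of 4) and stellate cell quiescence (0.26, 0 of 6) lists lay at percentiles 99.96 and 98.8. The pigment list had 22 of 23 members within 2-fold. The integrated stress response list (median -0.08, 19 of 21 within 2-fold) and the p53 target list (median -0.16, 18 of 19 within 2-fold) lay at percentiles 78.5 and 40.3 of random lists, although PPP1R15A (2.43-fold) and BBC3 (2.60-fold) were higher in the library labelled MP41. The fibrillar collagen list had a median of 1.04. The highest share of stellate-like RNA was then taken off each gene with all members kept. The collagen median became -1.31, and those of the cytokine, TGF-beta, YAP and interferon lists -0.25, -0.37, -0.00 and 0.16. In that order the lists lay at percentiles 0, 62.3, 10.1, 96.1 and 99.9 of random lists. The stellate cell quiescence, MHC class II and epithelial lists lay at percentiles 99.4, 97.8 and 70.4. The highest share is set by 1 gene, OSMR, and left 7 of 14 collagen members at 0 counts in a library, against 1 before. At the 1.21% share the medians were -0.69, -0.17, -0.33, 0.12 and 0.28, at percentiles 0.19, 71.8, 14.2, 99.7 and 100. This share too left members at 0 counts in a library: 6 of 14 for collagen, 3 of 8 for cytokines and 3 of 14 for TGF-beta. It is also above the median of 0.684% over the 61 genes that set it. Medians below 0 after either share was taken off therefore do not show lower expression in the library labelled MP41. TMM scaling raised the log2 ratio of all genes by a median of 0.17.

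Cell cycle phase calls differed in the same direction as the phase genes. In cells thinned to 4500 UMIs, 4.90% (interval 4.23 to 5.63%) of uveal melanoma-like cells of the library labelled MP41 were called S phase and 17.2% G2 or M, against 19.6% (18.4 to 20.9%) and 28.3% in the library labelled LX2. Of stellate-like cells, 43.6% were called S phase and 31.9% G2 or M. With all UMIs the S phase shares were 4.58%, 20.7% and 42.3%. Free RNA from cycling cells enters such calls. That of stellate-like cells, which held more S phase calls, would raise phase genes in the library labelled MP41, where they were lower. With its highest share taken off, the S phase and the G2 and M list medians were -1.05 and -0.71. This argues against stellate-like RNA as the source of these lower medians. The part of other free RNA, and of any free RNA in the phase calls, is open.

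**Figure D4:**
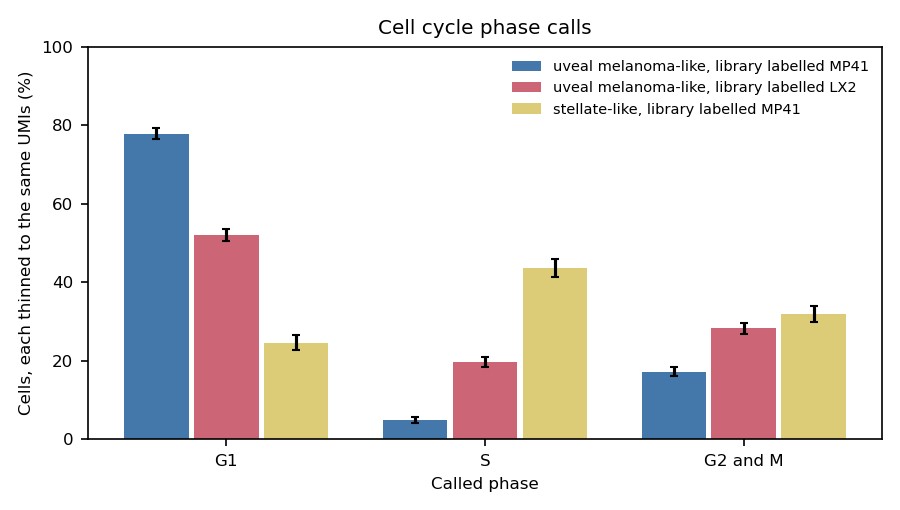
Share of cells (%) called in each cell cycle phase after thinning to 4500 UMIs, with exact binomial 95% intervals. The S phase share is 4.90% and 19.6% in uveal melanoma-like cells of the libraries labelled MP41 and LX2 and 43.6% in stellate-like cells.

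Communication between the cell types was the purpose the series states, and 148 ligand and receptor pairs were examined. With the libraries as sender and receiver, 35 pairs had both genes at 10 CPM or more from the library labelled MP41 to the library labelled LX2 and 18 the other way, but both libraries hold uveal melanoma-like cells. By class within the library labelled MP41, a choice made after the classes had been seen, 30 pairs passed from uveal melanoma-like to stellate-like cells and 39 the other way, of which 28 and 36 were above the level that free RNA of the other class may bring. Pairs were ranked by the product of their CPM among those with a ligand at least 4-fold higher in the sender. From uveal melanoma-like cells the leading pairs were osteopontin with integrin beta 1 and with CD44 (SPP1 at 773 against 25.4 CPM, ITGB1 at 580.3 and CD44 at 524 CPM in the receiver), LGALS3 with LGALS3BP, and GDF15 with TGFBR2 (32.2 CPM in stellate-like cells). LGALS3BP stood at 184 CPM in the receiver and 193 CPM in the sender. GDF15 with GFRAL was among the examined pairs and did not pass, as GFRAL stood at 0 CPM in both classes. From stellate-like cells they included COL1A1 with CD44 (193 CPM in the receiver), the growth factors MDK (219 against 3.11 CPM) and PTN (162 against 1.21 CPM) with NCL, and FN1 with CD44. Expression of both genes of a pair does not measure signalling.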

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

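The tests of the cell mixture, of stellate-like RNA as a source of GDF15, of free RNA and of the best mixture of classes were chosen after the results had been seen. The tests of depth and cell cycle and the test over all genes were set before their results, that in cells of like depth after the other values were known. The comparison of uveal melanoma-like cells between libraries was planned, and that of stellate-like with uveal melanoma-like cells was not.

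A signal outside the class comparisons came from the cells left out of both classes in the library labelled MP41, where a cluster with markers of both classes made up 5.86% of cells and an unnamed cluster 1.205%. The unnamed cluster, led by PLCG2, MALAT1 and GOLGA8A, held uveal melanoma markers at 140% of the highest named cluster and stellate markers at 3.56%, and was left unnamed by the depth clause of the naming rule. Its GDF15 stood at 6211 CPM at a median of 4698 UMIs, beside that uveal melanoma-like profile. In the similar cluster of 64 cells, found with the library clustered alone, MALAT1 stood at 274205 CPM against 25937 CPM in the rest. NEAT1 stood there at 60226 against 6352 CPM. The quality of the cells in these clusters was not tested, and their GDF15 level is not read as that of a separate kind of cell.

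For the cluster with both markers, free RNA at an even level is argued against by 56 stellate genes that the naming rule does not use, at a median of 28.7% of their stellate-like level (range 22.1 to 40.5%), against at most 2.43% in uveal melanoma-like cells of the library. The 12.6-fold gap in the naming markers decides nothing, since the rule itself parts these cells. A test over all genes could not decide whether it holds droplets of 2 cells, because the uveal melanoma-like profile alone left only 7.62% of 2559 genes over 2-fold away. Of the 195 genes that did differ over 2-fold from that profile, 100% lay within 2-fold of a mixture of the classes with 73.4% uveal melanoma-like RNA, which droplets of 2 cells would give. The median of 22061 UMIs lay between the 17387 of uveal melanoma-like cells and the 25495 of simulated pairs. With the library clustered alone, the mixed cluster held 606 cells (9.01%) at a median of 13563.5 UMIs, below that of uveal melanoma-like cells. Depth therefore does not decide the question. Free RNA that differs between droplets and cells that share both programs were not tested.

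Stellate-like cells lay in the library labelled MP41 and, with 1 exception, not in the library labelled LX2. A swap of 2 pure cultures is argued against by the 58.4% of uveal melanoma-like cells in the former. Free RNA is argued against by 5 lineage genes that the naming rule does not use, at a median of 3.77% of their level in the whole library (range 2.79 to 27.2%), while the naming markers, at most 2.61% of the highest cluster, are bounded by that rule and decide nothing. A candidate explanation is that the library labelled MP41 came from both lines grown together and the library labelled LX2 from MP41 alone, which needs few stellate-like cells in the latter, and 0.0256% were found. This is a hypothesis from the same data, and no condition is assigned from it.

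GDF15 was 2.04-fold higher in uveal melanoma-like cells of the library labelled MP41. Depth is argued against by ratios of 1.91 to 2.10 within 4 bins of cells of like depth. RNA from stellate-like cells is argued against by their GDF15 level at 4.65% of that in the library labelled LX2. Ratios of 1.62 and 2.003 within the clusters of cycling cells argue against cell cycle makeup as the whole source, but not as a part. These clusters, lower in GDF15, held 284 and 368 cells of the library labelled MP41 and 644 and 487 of the other. The ratio of 2.04 in thinned cells decides nothing, since thinning leaves shares of UMIs unchanged. Library preparation or sequencing batch cannot be told apart from the label, since there was 1 library per label. A biological difference between the cultures stays open and untested for the same reason.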

How the results depend on the processing

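Settings that use class comparisons were chosen after seeing the data. No paired analysis was possible because each label has 1 library. Counts moved with the rule itself. The count higher in the library labelled MP41 was 83, 752 and 505 at a floor of 50 CPM, a floor of 1 CPM and a ratio of at least 2, 367 with the mean of each cell's CPM and 14 with only the most common named class. That higher in the library labelled LX2 was 0 with TMM scaling, with only the most common named class, at a floor of 50 CPM and at a ratio of at least 8, then 2 without mitochondrial and ribosomal genes, 4 with the mean of each cell's CPM and 4 in thinned cells, 16 at a floor of 1 CPM and 160 at a ratio of at least 2. For stellate-like cells the counts were 521, 2173, 2730 and 697 at a floor of 50 CPM, a floor of 1 CPM, a ratio of at least 2 and a ratio of at least 8, and for uveal melanoma-like cells 253, 1399, 1447 and 372. Between libraries, uveal melanoma-like cells gave 4, 51, 78 and 6 genes higher in the library labelled MP41 at these settings. In the library labelled LX2 they gave 17 at a floor of 1 CPM and 163 at a ratio of at least 2, and 1 each without mitochondrial and ribosomal genes, in thinned cells and in cycling clusters only. With stellate-like RNA taken off at the 95th percentile share they gave 9 and 1 genes, and at the highest share 9 and 11. The GDF15 ratio of the libraries was 1.69 with TMM scaling, 1.36 with the mean of each cell's CPM, 1.39 in thinned cells and 2.04 with only the most common named class. In uveal melanoma-like cells it was 2.30 with TMM scaling, 2.15 without mitochondrial and ribosomal genes, 2.10 with the mean of each cell's CPM, 1.997 in cycling clusters only, 2.01 with only cells with no stellate UMI, which kept 37.2% and 96.3% of cells, and 2.07 and 2.09 with stellate-like RNA taken off at the 2 shares. It stayed above 1 in every setting run. Pairs from the library labelled MP41 numbered 21 with only the most common named class, 12 at a floor of 50 CPM and 89 at 1 CPM, and pairs from the library labelled LX2 5 and 67. By class they numbered 6 and 77 from uveal melanoma-like cells and 11 and 90 from stellate-like cells at these floors. Counting RAB27A as background left 28 and 34 pairs. The uveal melanoma-like share of the library labelled MP41 was 52.9% with no cell filter, 60.6% with the strict filter, 59.7% at resolution 0.2 and 59.6% with naming without the depth clause, and its stellate-like share 32.9% with the strict filter and 31.7% with each library clustered alone. The stellate-like share of the library labelled LX2 was 0% with the strict filter and with each library clustered alone. The immune list's median between libraries turned from 2.18 to -0.86 with only the most common named class, for a list with 2 measured genes in the main comparison. The causes were not tested beyond what a rule or a smaller set of cells fixes by construction. With 1 library per label, depth limits only the low genes, and the spread between cultures is unknown.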

Other observations

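The lists of STAT3 and NF-kB targets and of heat shock genes were chosen after the data had been seen. The 4 list tests below and the first test with stellate-like RNA taken off were set before their results were seen, and that with all members kept after. Of the members of the STAT3 and NF-kB lists, CXCL8 had been seen when these were written.

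In uveal melanoma-like cells, 7 of 14 measured IL-6 family and STAT3 target genes were at least 2-fold higher in the library labelled MP41, with a median log2 ratio of 1.11. The feedback inhibitor SOCS3 stood at 15.1 against 3.46 CPM, STAT3 itself at 120 against 46.6 CPM and JUNB at 198 against 73.6 CPM. A2M and CEBPD, which prompted the list, were left out of it. Of 12 measured NF-kB target genes, 5 were at least 2-fold higher there (median 0.85), among them ICAM1 at 108 against 53.3 CPM. Heat shock genes lay the other way, with a median of -0.61, 2 of 16 members at least 2-fold lower in the library labelled MP41 and 14 of 16 within 2-fold, and HSPH1 at 26.3 against 63.2 CPM. Among ligands in stellate-like cells, IL1B stood at 131 CPM and IL11 at 23.5 CPM, with LIF at 6.19 and IL6 at 4.38 CPM.

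A hypothesis is that genes driven by inflammatory cytokines are higher, as GDF15 is, in the uveal melanoma-like cells of the library labelled MP41. The medians of the STAT3 and NF-kB target lists lay at percentile 100 of matched random lists, as did those of the fixed TGF-beta, cytokine, YAP, interferon and collagen lists. With the highest share of stellate-like RNA taken off and all members kept, those fixed lists lay at percentiles 10.1, 62.3, 96.1, 99.9 and 0. The fixed stellate cell quiescence list lay at percentile 98.8 before and 99.4 after. For the STAT3 and NF-kB lists, percentiles of 100 and 99.8 with that share taken off decide nothing, as members fell out. With all members but CXCL8 kept both lists lay at percentile 100, at medians of 0.63 and 0.33, which argues against that RNA as their whole source but not as a part. Integrated stress response and p53 target genes, both known to go with GDF15, lay at percentiles 78.5 and 40.3, which argues against either list being higher as a whole. The lists share their direction with the library, so batch stays open, and whether stellate-like cells act on the uveal melanoma-like cells may not be read from 1 library per label.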
